A study of Mus musculus with 6 samples.

How the data were processed

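The 4 gene-expression libraries came from ovalbumin-specific OT-II CD4+ T cells, WT or heterozygous for the M318R knock-in of Tgfbr1, the type I TGF-beta receptor. Per the labels, donor cells were moved into CD45.1 WT hosts that drank water with 1.5% ovalbumin for 7 days, and donor T cells (CD45.2+CD45.1-CD4+CD8-TCRβ+) were sorted from Peyer's patches on day 8. The groups were WT (libraries WT 1 and WT 2) and mutant (libraries mutant 1 and mutant 2), taken from the labels. Another 2 WT samples, labelled as hashtag libraries, came without matrices of their own; the antibody counts in the WT matrices, which are described at the end, may be theirs. The design text also describes peanut gavage and rapamycin experiments, and the labels do not place these libraries in either.

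The deposited values are UMI counts per gene and cell in 10x 3′ single-cell matrices, made by the authors with Cell Ranger 6.0.0 on mm10 and Seurat 4, per the submitters' processing notes. The matrices hold 32285 genes and 4803 cell barcodes. The WT matrices also hold 3 antibody tags (301, 302 and 303), and the mutant matrices hold none, so handling with hashtag antibodies and genotype cannot be told apart. The labels do not say what the tags mark, nor whether each library is a separate animal. All p-values therefore measure the spread between these libraries, which may be technical.

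Cells were kept with at least 500 detected genes and at most 10% mitochondrial UMIs (3108 of 4803 barcodes), and the 31 doublets that Scrublet called per library in scanpy 1.11.5 were left out. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen (1792 after leaving out T cell receptor, immunoglobulin, mitochondrial, ribosomal-protein and predicted genes), and cells were grouped by Leiden clustering (leidenalg 0.10.2) at resolution 0.8 on 30 principal components and 15 neighbours, with seed 0. A cluster took a cell type's name when at least 3 of the type's markers were among its 50 leading genes with at least 2-fold enrichment, and otherwise kept its number. A cluster named after epithelial cells (145 cells) was left out, leaving 2932 kept T cells with 11789165 and 5498850 UMIs in WT 1 and WT 2 and 7528778 and 1622879 in mutant 1 and mutant 2. That cluster may also hold T cells, since 45.5% of its cells had a Cd3 UMI, so it is an imperfect negative for background. The exclusions from the variable genes, details of the naming rule and the use of all barcodes as Scrublet's input were set after the matrices had been seen.

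UMI counts were summed per library, genes were filtered with filterByExpr, scaled by TMM, and tested with edgeR 4.0.16's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, mutant minus WT. The same test was run within every class with at least 20 kept cells in every library: Tfh-like cells (T follicular helper, clusters 1 and 3), naive or memory-like cells, cluster 0, and cluster 1 alone. The difference of the genotype effect between the 2 most abundant classes, Tfh-like cells and cluster 0, was tested as an interaction with library as a block. By mistake the pair of Tfh-like and naive or memory-like cells was fitted first, and it is kept as an added alternative. CPM are TMM-scaled, and fitted log2 values use a prior count of 2. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, anndata 0.12.19, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and DESeq2 1.42.0.

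On simulated counts for 10612 genes in the comparison of all kept T cells, 200 genes were changed by known folds. There edgeR recovered 77.6% of the 2-fold and 97.0% of the 4-fold changes with 9 false calls. The same simulation for 8947 genes in Tfh-like cells gave 63.3% and 95.9%. For 5814 genes in naive or memory-like cells it gave 51.6% and 85.1%, for 8398 genes in cluster 0 66.3% and 99.0%, and for 8298 genes in cluster 1 66.0% and 90.6%. Each simulation drew every gene at the common dispersion (0.0114 over all kept T cells). It held no dispersion of single genes and no difference in cell mix between libraries, so these rates may be better than in the real data.

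Gene lists were tested with limma's camera at a preset correlation of 0.01 when at least 5 members were tested, and again with an estimated correlation and with fry. The marker lists covered Tfh, regulatory (Treg), Th1, Th2, Th17, naive or memory, proliferating, interferon-signature, cytotoxic, innate-like, NK or innate lymphoid, B, plasma, myeloid, epithelial, stromal and red blood cells. The others covered TGF-beta components, genes induced by TGF-beta, genes repressed by TGF-beta, type 2 Tfh cells, mTORC1, glycolysis, sterol synthesis, ribosomal proteins, nuclear respiratory-chain subunits, mitochondrially encoded genes, interferon-stimulated genes, immediate-early and stress genes, T cell receptor signalling, inhibitory receptors and anergy, cytokines, homing, S phase, G2 and M phase, apoptosis, donor sex and the OT-II receptor. Lists, tests, main settings and the naming rule were fixed before the data were examined, apart from the exceptions stated. The rule named the 10 largest rises and the 10 largest falls past the threshold with no overlap between genotypes, without predicted genes and receptor segments; 20 key genes; up to 4 members per list; and the 5 largest changes per direction within a class. Other genes are stated to have been chosen after their values were seen. Single-gene results for 2 of the key genes are not reported here.

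Shares of kept T cells carry Wilson 95% intervals, which cover counting error only, as do limits for a count of 0, set at 3 counts. Shares of cells with a UMI were taken after thinning each cell to 1500 UMIs, leaving out 2 and 4 shallower cells in WT 1 and WT 2 and 4 and 15 in mutant 1 and mutant 2. Differences of shares were tested with a two-sided exact permutation test, whose smallest possible p for 2 against 2 libraries is 0.333. Skil, Pmepa1, Ascl2 and Id1 were added to the UMI shares after their expression had been tested. Gene coordinates come from GENCODE vM21 on GRCm38, and all 150 of the named genes matched by identifier.

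Alternatives chosen in advance were DESeq2 size factors, the DESeq2 Wald test, no filter on low counts, a replicate block, leaving out each library, at least 200 genes, at most 5% mitochondrial UMIs, doublets kept, other cell types kept, thinning, Leiden resolutions of 0.5 and 1.2, genes centred within each library, cell cycle genes left out of the variable genes, thinning to 750 UMIs and no thinning. Alternatives added after seeing the data were doublets called on passing cells, leaving out the shallow cluster 8, equal cluster shares (156, 358, 326 and 87 cells from WT 1, WT 2, mutant 1 and mutant 2, over 8 clusters), clustering without the 118 genes past the threshold (1717 variable genes), cluster 1 alone, the interaction pair fitted by mistake, and cluster 1 against cluster 0. Equal cluster shares left out clusters 9, 10 and 11, which held only 3, 0 and 1 cells in mutant 2. These are the cluster with most Treg markers, the interferon-like and the proliferating-like cells. With a library left out, a lone library is assumed to vary like the other group.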

Results

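Gene expression was measured in single OT-II CD4+ T cells, which carry a receptor for an ovalbumin peptide, after transfer into WT hosts that drank ovalbumin. The cells were WT or heterozygous for an M318R knock-in in Tgfbr1 that models Loeys-Dietz syndrome, and all were recovered from Peyer's patches, the lymphoid follicles of the small intestine. Each genotype had 2 libraries. Kept T cells numbered 1269 in WT 1, 621 in WT 2, 864 in mutant 1 and 178 in mutant 2, with 11789165, 5498850, 7528778 and 1622879 UMIs. Median UMIs per kept cell were alike, at 8784 and 8550 in the WT libraries and 8514 and 8982 in the mutant libraries. Before filtering, barcodes over 10% mitochondrial UMIs made up 25.5% and 37.4% of the WT libraries and 41.4% and 22.0% of the mutant libraries.

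Tgfbr1 (ENSMUSG00000007613, chromosome 4, 47353222 to 47414931, plus strand) encodes the receptor kinase that carries the mutation. It gave 31.9 and 26.7 CPM in the WT libraries and 28.3 and 16.6 CPM in the mutant libraries, a log2 fold change of -0.26 ± 0.20 (SE) with an adjusted p of 0.631 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A knocked-in point mutation leaves 3′ tags unaltered, so these counts do not check the genotype labels. The V beta 5 family of the OT-II receptor made up 94.1% and 93.7% of V beta segment UMIs in the WT libraries and 94.2% and 98.3% in the mutant libraries. Its V alpha 2 family was less dominant. It had 36 and 21 UMIs in the WT libraries, against 20 and 14 for other V alpha segments. In the mutant libraries it had 19 and 6, against 8 and 6. The V beta share alone therefore does not settle the identity of the receptor, and the V alpha counts are few. Xist and Y-linked transcripts were present in every library, with Xist at 486 and 557 CPM in the WT libraries and 409 and 450 CPM in the mutant libraries. Without TMM scaling, Y-linked genes together stood at 125 and 132 CPM in the WT and 191 and 167 CPM in the mutant libraries. Xist was thus lower and Y-linked genes higher in both mutant libraries. The mix of donor sexes may therefore differ with genotype, which was not tested. The donor-sex list, which joins Xist with Y-linked genes, passed upwards as a set (median log2 fold change 0.39, 3 of its 6 genes past the threshold adjusted over the list alone, camera adjusted p = 0.0394, adjusted p = 0.673 with an estimated correlation). That call was lost without WT 1 and without mutant 1, each at a camera adjusted p of 0.216, and at equal cluster shares (0.0776) and without the shallow cluster (0.0878). Ddx3y led it at 0.61 (edgeR adjusted p = 0.0606), which passed without mutant 2 (0.72, edgeR adjusted p = 0.00288; 0.00288 to 1 over all alternatives).

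The comparison of all kept T cells asks which transcripts differ when T cells themselves carry the mutated receptor. Among the genes that fell were several of the feedback arm of the TGF-beta pathway. Smad7 and Pmepa1, which TGF-beta induces and which restrain its receptors and Smads, fell, as did Skil, a Smad-bound repressor. Foxp3, the lineage factor of regulatory T cells, and Ahr, a ligand-activated factor that TGF-beta raises in T cells, fell as well. Acod1, which makes itaconate, and the T follicular helper (Tfh) factor Ascl2 rose. The test covered 10612 genes. Of these, 65 rose and 53 fell in mutant cells, and 1258 had an unadjusted p under 0.05. Libraries did not overlap between genotypes for any of the 118 genes past the threshold, and for 44.9% of all tested genes, where chance gives 33.3%. Leaving out WT 1 reduced the calls to 21 and 15, without WT 2 they were 127 and 84, without mutant 1 they were 63 and 65, and without mutant 2 they were 242 and 169.

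Smad7 (ENSMUSG00000025880, chromosome 18, 75367529 to 75395935, plus strand) fell from 60.2 ± 18.2 CPM (SD, n = 2) to 23.9 ± 6.49 CPM (SD, n = 2), a log2 fold change of -1.46 ± 0.22 (SE; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00223). Pmepa1 (ENSMUSG00000038400, chromosome 2, 173224458 to 173276533, minus strand) fell from 90.9 ± 14.4 to 38.5 ± 3.97 CPM (-1.22 ± 0.16, edgeR adjusted p = 0.000982). Skil (ENSMUSG00000027660, chromosome 3, 31095058 to 31122577, plus strand) fell from 82.0 ± 0.303 to 46.4 ± 2.64 CPM (-0.80 ± 0.15, edgeR adjusted p = 0.0095). Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, plus strand) fell from 19.0 ± 8.53 to 4.00 ± 3.14 CPM (-1.93 ± 0.35, edgeR adjusted p = 0.00914), on 289 and 71 UMIs in the WT libraries and 46 and 3 in the mutant libraries. Ahr fell by 0.99 on the log2 scale (edgeR adjusted p = 0.0098). In all 4 cases of a library left out, Pmepa1 stayed past the threshold. Smad7 did not without mutant 1 (-1.11, edgeR adjusted p = 0.061; 2.55e-12 to 0.37 over all alternatives). Foxp3 lost its call without WT 1 (-1.37, edgeR adjusted p = 0.163; 1.43e-11 to 0.637 over all alternatives), as did Skil (-0.81, edgeR adjusted p = 0.146; 0.00013 to 0.288). Ahr lost it without WT 1 (-0.83, edgeR adjusted p = 0.32) and without mutant 1 (-0.81, edgeR adjusted p = 0.0884; 3.25e-05 to 0.32 over all alternatives).

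The 19 genes listed as induced by TGF-beta moved down as a set. Of 14 tested members, 5 fell and none rose at the threshold over all genes, and 6 fell and 2 rose adjusted over the list alone, with a median log2 fold change of -0.25 (camera adjusted p = 0.00492, adjusted p = 0.673 with an estimated correlation). Leaving out any 1 library kept this call, at camera adjusted p from 0.000694 to 0.0225. Genes repressed by TGF-beta, such as Ifng, Gzmb and Eomes, showed no change as a set (12 tested, 3 rose and 2 fell adjusted over the list alone, median -0.34, mean -0.06, camera adjusted p = 0.600). Among 14 tested pathway components the integrin Itgb8, which activates latent TGF-beta, rose (18.1 ± 4.83 to 37.4 ± 15.1 CPM, edgeR adjusted p = 0.0107), while Smad7 and the co-receptor Tgfbr3 (-0.91 ± 0.20, edgeR adjusted p = 0.0358) fell. Itgb8 is among the leading genes of cluster 3, so its rise may partly follow the share of that cluster. Cluster 3 made up 3.78% and 9.34% of kept T cells in WT 1 and WT 2 and 26.0% and 9.55% in mutant 1 and mutant 2. Adjusted over the list alone 1 component rose and 2 fell (median -0.15, camera adjusted p = 0.214, and 0.0432 without mutant 2). Itgb8 lost its call without WT 1 (0.89, edgeR adjusted p = 0.187) and without mutant 1 (0.59, edgeR adjusted p = 0.265; 2.02e-08 to 0.454 over all alternatives). Tgfbr3 lost it without WT 1 (-0.67, edgeR adjusted p = 1) and without mutant 1 (-0.61, edgeR adjusted p = 0.216; 0.000456 to 1 over all alternatives).

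**Figure D1:**
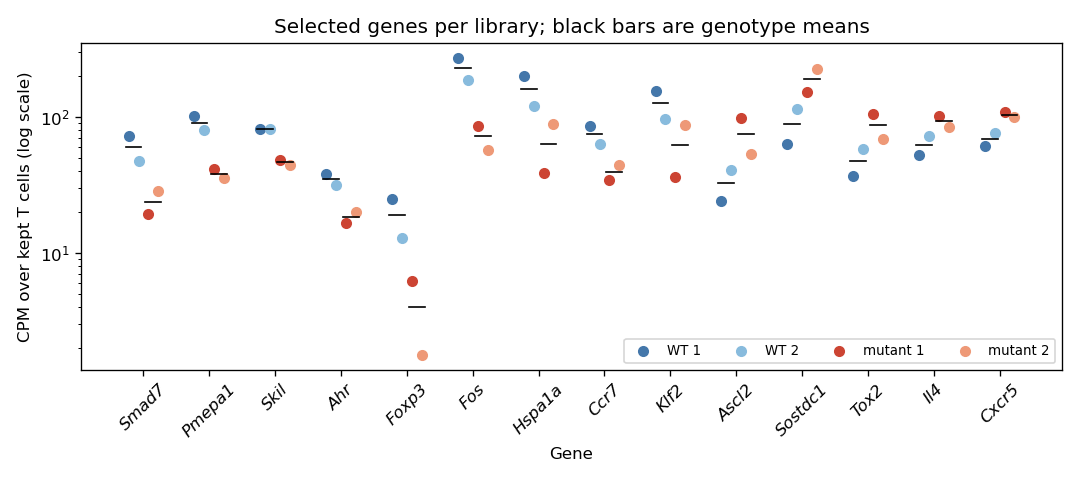
CPM (log axis) of selected genes in each of the 4 libraries, with black bars at the genotype means. Both mutant libraries lie below both WT libraries for Smad7, Pmepa1, Skil, Ahr, Foxp3, Fos, Hspa1a, Ccr7 and Klf2 and above them for Ascl2, Sostdc1, Tox2, Il4 and Cxcr5, of which Il4 and Cxcr5 did not pass the threshold.

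Tfh cells give help to B cells in germinal centres, and the study asks about their type 2 form, which makes IL-4. Ascl2, which starts the Tfh programme, rose (ENSMUSG00000009248, chromosome 7, 142966829 to 142969264, minus strand; 1.33 ± 0.24, edgeR adjusted p = 0.00831). Sostdc1, a Wnt antagonist made by Tfh cells, rose (1.09 ± 0.22, edgeR adjusted p = 0.0203), and so did Tox2, which supports Bcl6 (0.96 ± 0.20, edgeR adjusted p = 0.0285). Cxcr5, the follicle-homing receptor, was higher in both mutant libraries and just missed the threshold (0.61 ± 0.15, edgeR adjusted p = 0.0542), as did Il4 (0.62 ± 0.17, edgeR adjusted p = 0.0914; 52.4 and 73.1 CPM against 102 and 85.0 CPM). Il21 (0.40, edgeR adjusted p = 0.376), Bcl6 (0.40, 0.406), Pdcd1 (0.26, 0.559) and Gata3 (0.02, 0.975) did not pass. Without mutant 2, Cxcr5 (0.66, edgeR adjusted p = 0.005), Il4 (0.73, 0.00481), Il21 (0.60, 0.0209) and Bcl6 (0.56, 0.0494) passed. Without WT 2 Il4 passed (0.86, 0.0213), and without WT 1 or mutant 1 none of these did. Ascl2 lost its call without mutant 1 (0.76, edgeR adjusted p = 0.14; 3.99e-12 to 0.816 over all alternatives). Sostdc1 lost it without WT 1 (0.72, edgeR adjusted p = 0.352; 2.74e-09 to 0.816), as did Tox2 (0.63, 0.84), which also lost it without mutant 1 (0.57, 0.202; 1.33e-06 to 0.84).

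The Tfh markers rose as a set (15 tested, 3 rose and none fell at the threshold over all genes, 5 and 0 adjusted over the list alone, median 0.38, camera adjusted p = 0.0062, adjusted p = 0.673 with an estimated correlation). That call was lost without WT 1 (camera adjusted p = 0.138), without mutant 1 (camera adjusted p = 0.417) and at equal cluster shares (camera adjusted p = 0.519). The type 2 Tfh list leaned the same way without passing (15 tested, 2 rose adjusted over the list alone, median 0.37, camera adjusted p = 0.208). It passed without WT 2 (camera adjusted p = 0.0147) and without mutant 2 (camera adjusted p = 0.00215). The Th2 list did not pass (6 tested, 1 rose and 1 fell adjusted over the list alone, median 0.34, camera adjusted p = 0.486). Il13 and Il17a were too scarce to test: Il13 had 9 UMIs, all in 1 cell of WT 2, and all 45 UMIs of Il17a lay in 1 cell of mutant 1.

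Cells that home to lymph nodes and recirculate carry Ccr7, Klf2 and Lef1, and all 3 fell. The values were -0.98 ± 0.18 for Ccr7 (edgeR adjusted p = 0.0107; 74.5 ± 15.9 to 39.6 ± 7.03 CPM), -1.20 ± 0.28 for Klf2 (edgeR adjusted p = 0.0464) and -0.68 ± 0.14 for Lef1 (edgeR adjusted p = 0.0229). The gut-homing receptors Ccr9 (-0.99, edgeR adjusted p = 0.0648) and Itgae (-1.50, edgeR adjusted p = 0.152) did not pass. Ccr9 did without WT 2 (-1.38, 2.59e-06) and without mutant 2 (-0.87, 0.0346; 2.59e-06 to 1 over all alternatives). The naive or memory list fell (11 tested, 3 fell, 6 adjusted over the list alone, median -0.53, camera adjusted p = 0.00029), as did the homing list (26 tested, 2 fell, 2 rose and 7 fell adjusted over the list alone, median -0.36, camera adjusted p = 0.0117). Each had adjusted p = 0.673 with an estimated correlation. Both lists kept their camera calls whichever library was left out, but not at equal cluster shares (camera adjusted p = 0.562 and 0.617). The selectin ligand Selplg also fell (-0.73 ± 0.16, edgeR adjusted p = 0.0367). Without WT 1 the calls of Ccr7 (-0.72, edgeR adjusted p = 0.377), Klf2 (-0.77, 0.22), Lef1 (-0.56, 0.999) and Selplg (-0.54, 1) were lost. Without mutant 1 those of Ccr7 (-0.76, edgeR adjusted p = 0.0871), Klf2 (-0.54, 0.211) and Selplg (-0.50, 0.142) were lost. Over all alternatives adjusted p ran from 2.18e-06 to 0.794 for Ccr7, 1.67e-10 to 0.999 for Klf2, 0.00113 to 0.999 for Lef1 and 0.000415 to 1 for Selplg.

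Some markers of regulatory and Th1 cells fell. Beside Foxp3, the regulatory T cell receptor Gpr83 (-1.67 ± 0.22, edgeR adjusted p = 0.000881) and the actin-capping Capg (-0.76 ± 0.17, edgeR adjusted p = 0.037) fell, while Itgb8 rose. Ikzf2, a Treg factor that activated and Tfh cells also express, did not change (-0.04, edgeR adjusted p = 0.947), nor did Il10 pass (-1.09, edgeR adjusted p = 0.287), except without WT 2 (-1.58, 0.00178; 0.00178 to 1 over all alternatives). Of 10 tested Treg markers 2 rose and 5 fell adjusted over the list alone (median -0.54, camera adjusted p = 0.0117, adjusted p = 0.673 with an estimated correlation), a call lost without mutant 2 (camera adjusted p = 0.116) and at equal cluster shares (0.0703). Equal cluster shares left out the cluster with most Treg markers, so the loss in that setting may follow from its absence. Nkg7, a granule protein of cytotoxic and Th1 cells, fell (-1.56 ± 0.18, edgeR adjusted p = 0.000525), as did the chemokine Ccl5, while Tbx21 (0.65, edgeR adjusted p = 0.778) and Ifng (0.54, 0.256) did not pass. Ifng was higher in both mutant libraries, and Tbx21 rested on 11 and 9 UMIs in the WT and 6 and 9 in the mutant libraries. Of 9 tested Th1 markers 1 rose and 3 fell adjusted over the list alone (median -0.55, camera adjusted p = 0.0409, adjusted p = 0.673 with an estimated correlation), which was lost without WT 1 (camera adjusted p = 0.0784), mutant 1 (0.116) and mutant 2 (0.116). Ramp1, a neuropeptide co-receptor on the Th17 list, fell (-1.75 ± 0.19, edgeR adjusted p = 0.000305), and its list of 6 tested genes did not pass (1 rose and 1 fell adjusted over the list alone, median -0.04, camera adjusted p = 0.362, and 0.0267 without mutant 1). Nkg7 is among the leading genes of cluster 7 and Ramp1 among those of cluster 4, and both clusters were smaller in mutant libraries. Gpr83, Nkg7 and Ramp1 stayed past the threshold with every library left out in turn. Capg did not without WT 1 (-0.55, edgeR adjusted p = 1; 0.000147 to 1 over all alternatives).

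Immediate-early genes are switched on within minutes by receptor signals and by handling of tissue, and heat-shock genes by stress. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273, plus strand) fell from 229 ± 61.1 to 72.0 ± 20.3 CPM (-1.62 ± 0.19, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000543), and stayed past the threshold with any 1 library left out. The heat-shock gene Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156, minus strand) fell by 1.49 on the log2 scale (edgeR adjusted p = 0.0107), the phosphatase subunit Ppp1r15a by 0.93 (edgeR adjusted p = 0.0358) and the receptor-induced Nr4a1 by 0.92 (edgeR adjusted p = 0.0218). Nr4a1 is among the leading genes of cluster 4, which was smaller in mutant libraries. The immediate-early list fell (28 tested, 3 fell, 1 rose and 13 fell adjusted over the list alone, median -0.38, camera adjusted p = 3.21e-05, adjusted p = 0.673 with an estimated correlation), and did so with any library left out. The list of T cell receptor targets did not (20 tested, 2 rose and 3 fell adjusted over the list alone, median 0.06, mean -0.00, tested direction down, camera adjusted p = 0.600), although it fell without mutant 1 (camera adjusted p = 0.0287) and rose without mutant 2 (0.0432). Hspa1a lost its call without mutant 1 (-0.88, edgeR adjusted p = 0.0865; 2.96e-16 to 0.944 over all alternatives). Nr4a1 lost it without WT 1 (-0.59, edgeR adjusted p = 0.999; 6.85e-06 to 0.999). Ppp1r15a lost it without WT 1 (-0.50, edgeR adjusted p = 1) and without mutant 1 (-0.80, 0.139; 1.46e-05 to 1).

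The 10 largest rises ran from 2.09 to 4.06 on the log2 scale: Acod1 (ENSMUSG00000022126, chromosome 14, 103046977 to 103056573, plus strand), the RNA-binding Arpp21, the secreted glycoprotein Stc2, the amino-acid transporter Slc7a10, the sugar transporter Slc2a6, Samd12, the sarcomere gene Ttn, Fam71b, the interferon-induced GTPase Iigp1 and the keratin Krt17. Acod1 rested on 2 and 2 UMIs in the WT libraries against 37 and 4 in the mutant libraries. Fam71b (2.13 ± 0.28, edgeR adjusted p = 0.000881) and Slc2a6 (2.43 ± 0.39, edgeR adjusted p = 0.00318) kept their calls with any library left out. Acod1 was too scarce to test without mutant 1. Without WT 1 the calls of Acod1 (3.43, edgeR adjusted p = 0.163), Arpp21 (2.31, 0.999), Samd12 (1.88, 0.369), Ttn (1.97, 0.549) and Krt17 (1.50, 1) were lost, and without WT 2 that of Slc7a10 (1.96, 0.092). Without mutant 1 those of Arpp21 (3.42, edgeR adjusted p = 0.0884), Stc2 (1.24, 0.309), Slc7a10 (1.62, 0.424), Samd12 (2.21, 0.113), Iigp1 (0.64, 0.304) and Krt17 (1.74, 0.28) were lost, and without mutant 2 that of Ttn (1.78, 0.0759).

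The 10 largest falls ran from -5.32 to -2.08: the immunoglobulin light chain Igkc, the channel Trpm1, the GTPase activator Arhgap20, Ccl5, Emp1, the protease inhibitor Ctla2a, the claudin Cldn10, the vesicle protein Syp, the lymphocyte protease Ctsw and the enolase Eno3. Igkc, a plasma cell transcript that T cells do not make, stood at 155 CPM in WT 1 but 3.65 in WT 2, 2.44 in mutant 1 and 0.594 in mutant 2, so its fall was set by WT 1 (-0.90 without it, edgeR adjusted p = 1). Ctla2a (-2.52 ± 0.36, edgeR adjusted p = 0.00158) and Cldn10 (-2.34, 0.00318) kept their calls with any library left out. Ctla2a is among the leading genes of cluster 7 and Eno3 among those of cluster 4, both smaller in mutant libraries. Without WT 1 the calls of Trpm1 (-2.64, edgeR adjusted p = 0.0753), Arhgap20 (-2.42, 0.0528), Ccl5 (-1.37, 1), Emp1 (-1.94, 1), Syp (-1.48, 0.142) and Eno3 (-1.67, 0.32) were lost. Without mutant 1 those of Igkc (-7.10, edgeR adjusted p = 0.153), Trpm1 (-2.66, 0.0844), Ccl5 (-4.64, 0.103), Emp1 (-8.31, 0.0742), Syp (-2.37, 0.0788), Ctsw (-1.48, 0.0639) and Eno3 (-2.24, 0.0781) were lost.

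Metabolic and translation lists shifted by small amounts without any member past the threshold over all genes. Glycolytic enzymes, which fuel effector T cells and respond to mTORC1, rose (20 tested, 8 adjusted over the list alone, led by Pfkp and Hk2, median 0.38, camera adjusted p = 0.00029), a call lost without mutant 1 (camera adjusted p = 0.283) and at equal cluster shares (0.155). Mitochondrially encoded genes rose (13 tested, 2 adjusted over the list alone, median 0.20, camera adjusted p = 0.0062), lost without WT 1 (0.333) and mutant 1 (0.417). Shallow cells rich in mitochondrial UMIs (cluster 8) moved with them, at 0.788% and 3.70% of WT and 6.71% and 13.5% of mutant libraries, and without these cells the list still passed (camera adjusted p = 0.0134). Both lists had adjusted p = 0.673 with an estimated correlation. Ribosomal protein genes were lower (79 tested, 0 adjusted over the list alone, median -0.18, camera adjusted p = 3.21e-05, adjusted p = 0.720 with an estimated correlation), lost without WT 1 and at equal cluster shares (camera adjusted p = 0.617). Within classes this fall did not recur. The median was 0.05 in Tfh-like cells, 0.03 in naive or memory-like cells, -0.02 in cluster 0 and 0.04 in cluster 1, and the list did not pass. Nuclear respiratory-chain genes were lower (87 tested, 0 adjusted over the list alone, median -0.12, camera adjusted p = 0.00029, adjusted p = 0.749 with an estimated correlation), lost without mutant 2 (0.578). Targets of mTORC1, the kinase complex that rapamycin blocks, did not change as a set (57 tested, 5 rose and 1 fell adjusted over the list alone, median -0.08, camera adjusted p = 0.301), nor did sterol genes (25 tested, 0 adjusted over the list alone, median -0.09, camera adjusted p = 0.362).

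Cell-cycle genes of G2 and M phase rose (43 tested, 7 adjusted over the list alone, median 0.28, camera adjusted p = 0.000213, adjusted p = 0.673 with an estimated correlation), which was lost without WT 1 (camera adjusted p = 0.166) and at equal cluster shares (0.562). The proliferating-cell markers rose (16 tested, 7 rose and 2 fell adjusted over the list alone, median 0.82, camera adjusted p = 0.00492, adjusted p = 0.673 with an estimated correlation), although their member Stmn1 fell (-0.75 ± 0.15, edgeR adjusted p = 0.0203). The call of these markers was lost without mutant 1 and at equal cluster shares (camera adjusted p = 0.93). Equal cluster shares left out the proliferating-like cluster, so the losses of both lists there may follow from its absence. Stmn1 lost its call without WT 1 (-0.65, edgeR adjusted p = 0.625) and without mutant 1 (-0.78, 0.0526; 0.000653 to 0.794 over all alternatives). S phase genes did not change as a set (36 tested, 0 adjusted over the list alone, median -0.11, camera adjusted p = 0.135, and 0.00506 without mutant 2). The inhibitory-receptor and anergy list rose (15 tested, 1 rose, 4 adjusted over the list alone, median 0.32, camera adjusted p = 0.00492, adjusted p = 0.673 with an estimated correlation), lost without WT 1 (camera adjusted p = 0.0566), without mutant 1 (0.457) and at equal cluster shares (0.438). Its member Rnf128, a ubiquitin ligase of anergic T cells, rose (1.43 ± 0.31, edgeR adjusted p = 0.0324) but not without WT 1 (0.95, 1) or mutant 1 (1.23, 0.195; 7.75e-05 to 1 over all alternatives). The growth factor Csf1 rose (1.36 ± 0.20, edgeR adjusted p = 0.0017), except without mutant 1 (0.95, 0.0541; 2.22e-11 to 0.394 over all alternatives), while the cytokine list did not pass (18 tested, 2 rose and 2 fell adjusted over the list alone, median 0.11, mean -0.04, tested direction up, camera adjusted p = 0.984).

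Interferon-stimulated genes showed no set change (42 tested, 1 rose adjusted over the list alone, median -0.00, mean 0.05, tested direction up, camera adjusted p = 0.600), nor did the interferon-signature markers (14 tested, 0 adjusted over the list alone, median -0.04, camera adjusted p = 0.638). These lists changed with the library left out: interferon-stimulated genes rose without WT 1 (camera adjusted p = 5.97e-05) and mutant 2 (0.00132) and fell without WT 2 (0.0035), and the markers rose without WT 1 (0.0209) and fell without WT 2 (0.00102). Apoptosis genes did not change (22 tested, 0 adjusted over the list alone, median 0.04, tested direction down, camera adjusted p = 0.976), nor did OT-II receptor genes (5 tested, 0 adjusted over the list alone, median -0.04, camera adjusted p = 0.600). The B cell list did not pass (6 tested, 3 rose adjusted over the list alone, median 0.79, camera adjusted p = 0.0774, and 0.00129 without WT 2), though Ighm rose (0.67 ± 0.15, edgeR adjusted p = 0.0418), except without WT 1 (0.46, 1; 0.000865 to 1 over all alternatives). Fewer than 5 members were tested for the cytotoxic (4), innate-like (1), NK or innate lymphoid (1), plasma (2), myeloid (4), epithelial (4), stromal (1) and red blood cell (0) lists, and among these only Igkc of the plasma list passed over all genes. Over the 30 tested lists, 15 passed with camera at the preset correlation. With an estimated correlation 0 passed and 0 had an unadjusted p under 0.05, and with fry 1 passed (the OT-II receptor list, down, adjusted p = 0.00596) and 2 had an unadjusted p under 0.05. The Th1, homing and TGF-beta-induced lists lost their camera calls at estimated correlations of -0.0214, -0.0212 and 0.00605. These lie under the preset 0.01, so a larger correlation is not what removed those calls.

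Within classes, the fall of Fos recurred in cells of different kinds. The feedback genes Pmepa1 and Smad7 each passed in a single class, which does not show that their falls were limited to it. Smad7 fell by 1.69 on the log2 scale in Tfh-like cells without passing, on 19 and 18 UMIs in the WT and 11 and 1 in the mutant libraries. Its fall in cluster 0, where it passed, was 1.60. Tfh-like cells, naive or memory-like cells and cluster 0, an unnamed group led by Egr3 and Gpr183, each had enough cells. Fos fell in all 3, Pmepa1 in Tfh-like cells, Smad7 and Ahr in cluster 0, and Foxp3 in naive or memory-like cells. In Tfh-like cells, Il4, Il21, Bcl6 and Pdcd1 did not pass, but they are among the 50 leading genes of cluster 1 or 3, so the clustering partly sets their levels there. In Tfh-like cells (8947 genes) 9 genes rose and 9 fell, in naive or memory-like cells (5814 genes) 7 and 8, and in cluster 0 (8398 genes) 8 and 7. Counts moved with single libraries: without WT 1 they were 0 and 4, 1 and 1, and 2 and 2, and without mutant 2 they were 135 and 61, 14 and 19, and 6 and 6. Without WT 2 they were 13 and 12, 2 and 10, and 7 and 10, and without mutant 1 they were 43 and 29, 30 and 20, and 18 and 19. In Tfh-like cells without WT 1, edgeR gave 323 genes with an unadjusted p under 0.05.

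In Tfh-like cells Fos fell from 183 ± 4.61 to 73.3 ± 8.79 CPM (-1.27 ± 0.15, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00119) and passed in all 16 alternatives. Pmepa1 fell by 1.46 (edgeR adjusted p = 0.00539), with adjusted p = 0.0584 without WT 1 (1.35e-08 to 0.0806 over all alternatives). The GTPase regulator Arap2 rose from 94.4 ± 21.0 to 232 ± 74.2 CPM (1.38 ± 0.19, edgeR adjusted p = 0.00539), with adjusted p = 0.0834 without WT 1 (7.97e-28 to 0.676 over all alternatives). Acod1 (3.52), Iigp1 (2.46), Stc2 (1.86) and Fam71b (1.38) also rose, and Vim (-1.70), Fam3c (-1.54) and Hspa1a (-1.46) fell. Of these, Fam3c kept its call with any library left out. Without WT 1 the others except Vim lost theirs, with Acod1 at 2.98 (edgeR adjusted p = 0.771), Iigp1 at 2.30 (0.0547), Stc2 at 1.74 (0.22), Fam71b at 1.29 (0.201) and Hspa1a at -1.15 (0.381). Without WT 2 Acod1 (4.14, edgeR adjusted p = 0.0811) and Vim (-1.43, 0.219) lost theirs. Without mutant 1 the folds themselves shrank, to 0.26 for Iigp1 (edgeR adjusted p = 0.927), 0.45 for Stc2 (0.877) and -0.52 for Hspa1a (0.425), and Acod1 was too scarce to test. Iigp1 and Fam71b are among the 50 leading genes of cluster 3, where most Tfh-like cells lay in mutant 1 but not in the other libraries. Il4 (-0.07, edgeR adjusted p = 0.971), Cxcr5 (0.29, 0.657), Il21 (-0.12, 0.933), Bcl6 (-0.03, 0.999), Pdcd1 (-0.07, 0.978) and Smad7 (-1.69, 0.281) did not pass. Lists that passed were naive or memory (median -0.48), genes induced by TGF-beta (median -0.28, 3 fell adjusted over the list alone), glycolysis (median 0.19) and immediate-early (median -0.14), each at camera adjusted p = 0.0428 (adjusted p = 0.903 with an estimated correlation), and mitochondrially encoded genes (median 0.13, camera adjusted p = 0.0472, adjusted p = 0.985 with an estimated correlation).

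In naive or memory-like cells Foxp3 had 80 UMIs in the WT libraries and 0 in the mutant libraries, at least 5.37-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.00361; 0.999 without WT 1 and 0.0909 without mutant 1, too scarce to test without WT 2). Hspa1b (-1.64, edgeR adjusted p = 4.66e-06), Gpr83 (-1.91, 0.022), Sox4 (-2.45, 0.00361) and Syp (-3.24, 0.00165) fell. The ribosyltransferase Art2b (1.24 ± 0.17, edgeR adjusted p = 2.07e-06) rose and passed in all 11 alternatives. The IL-7 receptor Il7r (1.35, edgeR adjusted p = 0.0155), mt-Atp8 (0.87, 0.0113), Lars2 (0.82, 0.00605) and AY036118 (0.69, 0.00605) also rose. Without WT 1 every one of these calls but those of Art2b and Gpr83 was lost (edgeR adjusted p = 0.192 for Hspa1b at -1.19, 0.965 for Il7r at 1.31, and 0.999 for Sox4 at -2.15, Syp at -2.69, mt-Atp8 at 0.79, Lars2 at 0.64 and AY036118 at 0.49). Without WT 2 those of Il7r (1.33, edgeR adjusted p = 0.0536), mt-Atp8 (0.90, 0.135), Lars2 (0.94, 0.0694), AY036118 (0.86, 0.0694) and Gpr83 (-1.56, 0.446) were lost. Without mutant 1 those of Il7r (0.71, edgeR adjusted p = 0.666), Sox4 (-2.15, 0.0806) and Gpr83 (-1.33, 0.339) were lost, and without mutant 2 that of mt-Atp8 (0.67, 0.211). Smad7 (-0.67, edgeR adjusted p = 0.48) and Ccr7 (-0.15, 0.923) did not pass. They, Il7r, Gpr83 and Hspa1b are among the 50 leading genes of this cluster, which partly sets their levels. Syp also leads this cluster but was not among the variable genes used for clustering. Lists that passed were Treg (median -0.34, camera adjusted p = 0.000317, 0.860 with an estimated correlation), genes induced by TGF-beta (median -0.88, 8 of 12 fell adjusted over the list alone, camera adjusted p = 9.38e-05, 0.860), immediate-early (median -0.44, 9 fell adjusted over the list alone, camera adjusted p = 9.23e-05, 0.866), nuclear respiratory chain (median -0.16, 0.00348, 0.866) and mitochondrially encoded (median 0.26, 0.00842, 0.866). The Treg and TGF-beta medians stay the same with Foxp3 set at its bound.

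In cluster 0 Fos (-1.62, edgeR adjusted p = 3.44e-05) and Smad7 (-1.60 ± 0.25, 0.000766; 61.2 ± 2.66 to 18.5 ± 4.32 CPM) fell and kept their calls with any library left out. Ppp1r15a (-1.18, edgeR adjusted p = 0.0351), Ahr (-1.02, 0.0487) and the cold-shock protein Rbm3 (-0.79, 0.0103) also fell, and Fbn2 (1.91, 0.0351), Csf1 (1.39, 0.00185), Nrgn (1.25, 0.000361), H2-Q6 (1.08, 0.0412) and Atxn1 (0.86, 0.0351) rose. Ahr and Csf1 are among the 50 leading genes of cluster 0, which partly sets their levels. Each of these genes lost its call in at least 1 case. Without WT 1 these were Ppp1r15a (-0.60, edgeR adjusted p = 1), Ahr (-0.86, 1), Rbm3 (-0.77, 0.398), Fbn2 (1.33, 1), Nrgn (1.11, 0.0907), H2-Q6 (1.47, 0.0701) and Atxn1 (0.78, 1). Without WT 2 they were Ahr (-1.08, edgeR adjusted p = 0.132), Rbm3 (-0.84, 0.0583), Csf1 (1.12, 0.0587), H2-Q6 (0.91, 0.451) and Atxn1 (0.92, 0.223). Without mutant 1 the fold shrank for Csf1 (0.57, edgeR adjusted p = 0.589), Ahr (-0.62, 0.504) and Ppp1r15a (-0.81, 0.432), and stayed close for Atxn1 (0.79, 0.232). Without mutant 2 the calls of Ppp1r15a (-1.34, edgeR adjusted p = 0.0812), Rbm3 (-0.62, 0.0935), Fbn2 (1.58, 0.168) and H2-Q6 (0.92, 0.161) were lost. Lists that passed were genes induced by TGF-beta (median -0.50, 5 fell adjusted over the list alone, camera adjusted p = 0.00627), nuclear respiratory chain (median -0.11, 0.00711) and immediate-early (median -0.30, 10 fell adjusted over the list alone, 0.000343), each with adjusted p = 0.978 with an estimated correlation. Cluster 1 alone, the larger Tfh-like part, gave 45 rises and 20 falls in edgeR over 8298 genes. Its largest were rises of the mitotic motor Cenpe (3.06), Slc7a10, Sik1, Ccdc191 and Ica1l and falls of Vim (-2.05), Hspa1b (-1.53), Grhl1, Pmepa1 (-1.38) and Hspa1a (-1.32). These were not refitted with a library left out. Cenpe rested on 4 and 3 UMIs in WT 1 and WT 2 against 35 and 4 in mutant 1 and mutant 2, and Slc7a10 on 7 and 0 against 21 and 4. Hspa1b stood at 170 and 166 CPM against 24.9 and 140, and Hspa1a at 86.8 and 95.9 against 20.9 and 76.3. Both falls thus lay mostly in mutant 1. The immediate-early list of cluster 1 fell (median -0.22, camera adjusted p = 0.0106, adjusted p = 0.968 with an estimated correlation). Genes induced by TGF-beta did not pass as a list in cluster 1 (median -0.0796, camera adjusted p = 0.392). The pass in Tfh-like cells, which pool clusters 1 and 3, is therefore not free of their mix.

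**Figure D2:**
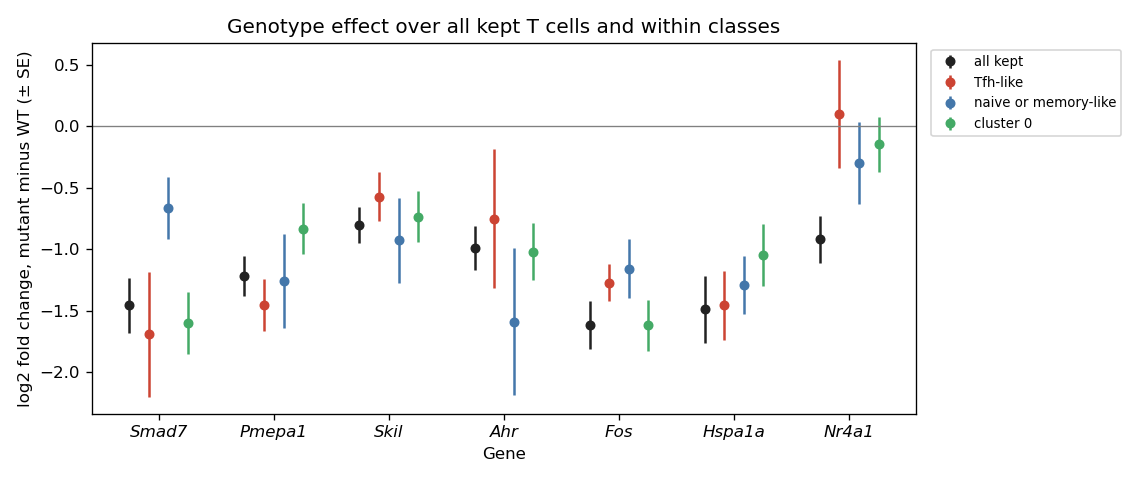
Log2 fold change, mutant minus WT, with its SE for 7 genes over all kept T cells and within 3 classes. Fos lies below 0 in every group (-1.27 in Tfh-like cells and -1.62 in cluster 0), while Nr4a1 did not pass within any class.

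Whether the mutation acts differently on Tfh-like cells (813 cells) and cluster 0 (706 cells) was tested directly. The estimated effect was higher in Tfh-like cells for Egr3, Rel and Nfkbia, which receptor and NF-kappaB signals induce, and for Arap2, Gadd45b, Cybb and Ms4a4b. That on S100a10 and the protease inhibitor Cst7 was lower there. Tfh-like cells lay mostly in cluster 1 in WT 1 (158 of 206), WT 2 (127 of 185) and mutant 2 (34 of 51) but in cluster 3 in mutant 1 (225 of 371), so these differences may be this mix. With cluster 1 in place of the class no gene passed in edgeR (8717 tested, 419 at an unadjusted p under 0.05). The difference was then -0.16 for Nfkbia and 0.42 for Rel (edgeR adjusted p = 1 each), against 0.66 and 0.96 with the class. It was 1.17 for Gadd45b (edgeR adjusted p = 0.636) against 1.63. It stayed close for S100a10 (-0.64, edgeR adjusted p = 0.113), Ms4a4b (0.72, 0.113), Cst7 (-1.08, 0.444), Arap2 (0.84, 0.444) and Cybb (2.25, 0.444). Egr3 is the first leading gene of cluster 0, so its effect there is partly fixed by the clustering and is not read. S100a10 is also among the 50 leading genes of cluster 0, and Cybb among those of cluster 3. Of these 9 genes only Arap2 passed within Tfh-like cells and none within cluster 0. Of 9250 genes tested in edgeR, the effect was higher in Tfh-like cells for 7 and lower for 2, with 471 at an unadjusted p under 0.05. S100a10 had effects of -0.48 in Tfh-like cells and 0.19 in cluster 0, a difference of -0.67 ± 0.12 (edgeR adjusted p = 0.00129). Ms4a4b had effects of 0.66 and -0.05 (difference 0.72 ± 0.13, edgeR adjusted p = 0.00129). Without WT 1 the counts were 2 and 0 with 353 at an unadjusted p under 0.05, without WT 2 they were 2 and 1, without mutant 1 they were 4 and 3, and without mutant 2 they were 17 and 8. Without mutant 1 all 9 genes lost their calls. The difference shrank for Cst7 (-0.34, edgeR adjusted p = 0.918), Arap2 (0.39, 0.777) and to a lesser degree Rel (0.61, 0.731) and Ms4a4b (0.54, 0.349). It did not shrink for S100a10 (-0.68, edgeR adjusted p = 0.0716), Gadd45b (2.53, 0.332) and Cybb (2.55, 0.583), and stayed close for Nfkbia (0.60, 0.519).

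Tfh-like cells made up 16.2% (14.3 to 18.4), 29.8% (26.3 to 33.5), 42.9% (39.7 to 46.3) and 28.7% (22.5 to 35.7) of kept T cells in WT 1, WT 2, mutant 1 and mutant 2 (Wilson 95% intervals). The means were 23.0 ± 9.59% in WT and 35.8 ± 10.1% in mutant libraries (SD, n = 2 each), and the libraries overlapped (exact permutation p = 0.667). Clustered without the 118 genes past the threshold, which could still name clusters, the shares were 17.3%, 31.7%, 43.4% and 29.2% (exact permutation p = 0.667). In 7 of 9 alternative clusterings, that one included in the 9, both mutant libraries lay above both WT libraries (differences of 12.3 to 15.9 percentage points, exact permutation p = 0.333), for example at 24.7% in mutant 2 against 22.5% in WT 2 at Leiden resolution 1.2. The difference of 12.8 percentage points was 5.64 without mutant 1, 6.01 without WT 1, 19.6 without WT 2 and 19.9 without mutant 2. Naive or memory-like cells made up 19.6%, 13.0%, 4.98% and 11.8%, without overlap (exact permutation p = 0.333, the smallest possible), and without the 118 genes 19.8%, 13.0%, 6.25% and 16.3%, with overlap (exact permutation p = 0.667). The difference of -7.95 points was -4.65 without WT 1, -11.2 without WT 2, -4.53 without mutant 1 and -11.4 without mutant 2. Among unnamed clusters, 4 and 7 fell and 0 and 8 rose without overlap (exact permutation p = 0.333 each). Cluster 4, led by Tnfrsf9 and Nr4a1, made up 18.6%, 10.8%, 4.17% and 5.06%. Cluster 7, led by Eomes and Slamf7, made up 5.28%, 5.15%, 2.78% and 3.93%. Eno3, Nr4a1 and Ramp1 are among the leading genes of cluster 4, and Nkg7 and Ctla2a among those of cluster 7. Their falls over all kept T cells may partly follow these shares. The cluster with most Treg markers, led by Gzmb, Ccr9 and Cxcr6 and holding Foxp3, made up 4.57%, 2.42%, 1.97% and 1.69%, and 4.50%, 2.25%, 1.97% and 1.69% without those genes (exact permutation p = 0.333). Interferon-like cells made up 5.60%, 0.966%, 1.62% and 0% (0 of 178 cells allows up to 1.69%; exact permutation p = 0.667), and proliferating-like cells 0.315%, 1.29%, 1.27% and 0.562% (exact permutation p = 1). The Tfh-like class lay mostly in cluster 1 in WT 1, WT 2 and mutant 2 and in cluster 3 in mutant 1.

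**Figure D3:**
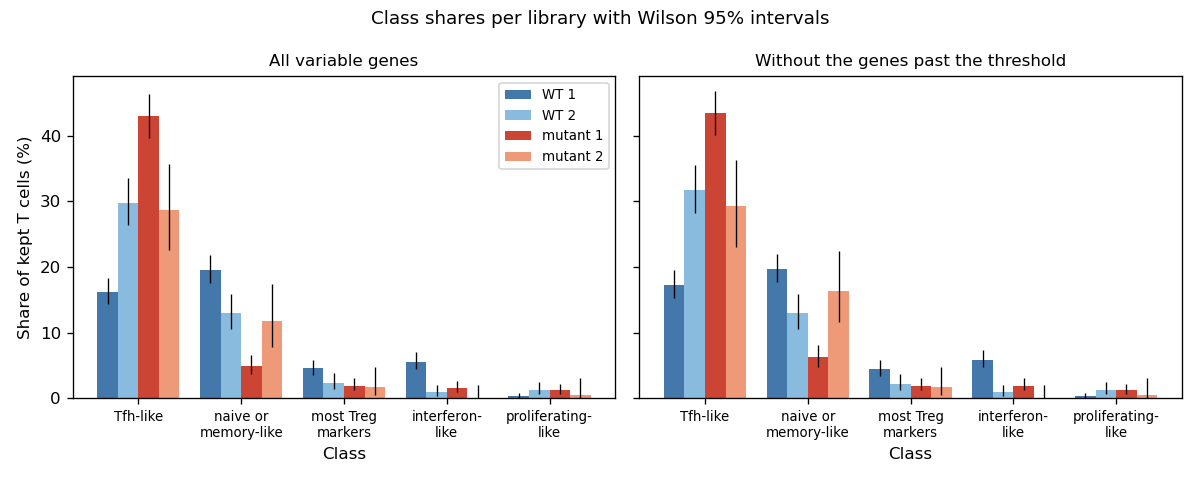
Share of kept T cells (%) in 5 classes per library, with Wilson 95% intervals, clustered with all variable genes and without the genes past the threshold. The Tfh-like share of mutant 2 (28.7%) lies between those of WT 1 (16.2%) and WT 2 (29.8%), and only mutant 1 (42.9%) lies above both, while mutant 2 also lay above both in 7 of 9 alternative clusterings.

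Counting cells with at least 1 UMI at 1500 UMIs per cell needs no classes. Il4 was detected in 7.02%, 8.59%, 11.98% and 9.20% of cells in WT 1, WT 2, mutant 1 and mutant 2, against 5.43% in the epithelial-named cluster. Cxcr5 was detected in 7.66%, 9.89%, 15.2% and 10.4% (7.75% in that cluster), Smad7 in 8.37%, 6.65%, 2.79% and 6.14% (5.43%), Ccr7 in 9.63%, 8.27%, 4.30% and 6.14% (0.775%) and Ccr9 in 5.84%, 3.57%, 1.98% and 1.84% (0%). Foxp3 was detected in 3.32%, 1.46%, 0.698% and 0% (0.775%), where finding no UMI in 163 cells allows up to 1.84% of such cells. The cluster may also hold T cells and is an imperfect background. Pmepa1 was detected in 12.5%, 11.5%, 5.93% and 3.07% (9.30%), Skil in 10.6%, 11.99%, 6.63% and 4.29% (3.10%), and Ascl2 in 2.21%, 4.38%, 9.54% and 4.91% (5.43%). The mutant shares of Pmepa1 and Foxp3 and the Ascl2 shares other than that of mutant 1 thus lay below the level in that cluster. So did Smad7 in mutant 1 and, narrowly, Cxcr5 in WT 1. Without thinning, Il4 was detected in 19.7%, 27.4%, 37.7% and 32.6% (21.4%) and Pmepa1 in 44.9%, 39.3%, 21.5% and 18.5% (29.0%). Median UMIs before thinning were 8784, 8550, 8514 and 8982 in the libraries and 7156 in that cluster (10720 in its 129 cells deep enough to thin). Of 20 key genes, 11 did not overlap between genotypes, where chance gives 33.3%, each with the smallest possible exact permutation p of 0.333.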

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

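The estimated effect of the receptor mutation differed between Tfh-like cells and cluster 0 for 9 genes, by a direct test of the difference in edgeR's quasi-likelihood framework with Benjamini-Hochberg adjustment. The pair of classes was set by abundance. S100a10, a partner of annexin A2, differed by -0.67 on the log2 scale (edgeR adjusted p = 0.00129) and Ms4a4b, a membrane protein of T cells, by 0.72 (0.00129). The receptor-induced factor Egr3 differed by 1.29 (edgeR adjusted p = 0.00968), but it is the first leading gene of cluster 0, so the clustering partly fixes its effect there. The stress gene Gadd45b differed by 1.63 (edgeR adjusted p = 0.011) and the GTPase regulator Arap2 by 0.92 (0.0154). The oxidase subunit Cybb differed by 2.34 (edgeR adjusted p = 0.0251), the NF-kappaB subunit Rel by 0.96 (0.0251), the protease inhibitor Cst7 by -1.16 (0.0265) and the NF-kappaB inhibitor Nfkbia by 0.66 (0.0483). Tfh-like cells lay mostly in cluster 1 in WT 1 (158 of 206), WT 2 (127 of 185) and mutant 2 (34 of 51) but in cluster 3 in mutant 1 (225 of 371), so the differences may be this mix. With cluster 1 in place of the class no gene passed in edgeR. Egr3 and Nfkbia then changed sign (-0.16 each, edgeR adjusted p = 1) and Rel shrank (0.42, 1), while S100a10 (-0.64, 0.113) and Ms4a4b (0.72, 0.113) stayed close. Without mutant 1 no call remained for these 9 genes. The difference was then smaller for Egr3 (0.32, edgeR adjusted p = 0.946), Cst7 (-0.34, 0.918), Arap2 (0.39, 0.777), Rel (0.61, 0.731) and Ms4a4b (0.54, 0.349). It was about as large or larger for S100a10 (-0.68, edgeR adjusted p = 0.0716), Nfkbia (0.60, 0.519), Cybb (2.55, 0.583) and Gadd45b (2.53, 0.332). Over all alternatives adjusted p ran from 0.000169 to 0.127 for S100a10. Without WT 1, S100a10 (edgeR adjusted p = 0.127), Gadd45b (0.6), Arap2 (0.0723), Cybb (0.056), Rel (1), Cst7 (0.524) and Nfkbia (0.056) lost theirs. Without WT 2, Ms4a4b (0.535), Egr3 (0.535), Arap2 (0.509), Cybb (0.216), Rel (0.0869), Cst7 (0.0869) and Nfkbia (1) did. Beyond this mix of clusters, no explanation was weighed for these genes.

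Antibody tags, which the report's comparisons do not use, gave a clear signal. Of kept T cells, 93.5% in WT 1 (1187 of 1269) and 90.2% in WT 2 (560 of 621) had 1 leading tag, and 4.26% and 6.28% were mixed. The labels do not say what the tags mark. Tags 301, 302 and 303 led in 449, 435 and 303 cells of WT 1 and in 134, 70 and 356 cells of WT 2. Tfh-like cells made up 16.5%, 18.9% and 13.2% of these in WT 1 and 35.1%, 22.9% and 30.9% in WT 2. No biological explanation was tested for the tags.

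The patterns below were weighed against technical causes. The test of whether genes that differ decide which cells are called Tfh-like was written down before its result; all the others were chosen after the pattern had been seen. Tests of the first pattern on its 5 fallen genes alone were replaced by tests of the whole list, since those genes had been picked by their fall, and the condition on single clusters was set after their values were known.

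The first pattern is the fall of genes that TGF-beta induces, tested as the whole list fixed in advance (14 genes). The list still passed at equal cluster shares (camera adjusted p = 0.00335) and within 2 single clusters, cluster 0 (0.00627) and the naive or memory-like one (9.38e-05). Shares of these clusters are therefore not its whole source. A changed mix of cells inside a cluster is not excluded, as the Treg list also fell in the naive or memory-like one (camera adjusted p = 0.000317). The list of genes induced by TGF-beta did not pass within cluster 1 (camera adjusted p = 0.392). It passed without the shallow cluster (camera adjusted p = 0.00722) and without mutant 2 (0.0225), which argues against either as its whole source; all of these calls rest on the preset correlation (adjusted p = 0.673 with an estimated one over all kept T cells). For single members less is excluded as to class shares. At equal cluster shares Pmepa1 (-1.30, edgeR adjusted p = 0.00406) and Smad7 (-1.20, 0.0197) stayed past the threshold. Foxp3 (-3.58, edgeR adjusted p = 0.0757), Skil (-0.83, 0.0604) and Ahr (-1.05, 0.162) did not, on fewer cells and without smaller folds. That setting left out the cluster with most Treg markers, which holds Foxp3, so the fold of Foxp3 there comes from cells outside it. When cells were thinned only Pmepa1 kept its call, on fewer UMIs. The folds of Foxp3 (-2.23, edgeR adjusted p = 0.0813), Skil (-0.95, 0.0671) and Ahr (-1.36, 0.055) were then no smaller and that of Smad7 (-1.24, 0.0897) was close, so these lost calls are no sign of an effect of depth. Only the 2 WT libraries carried antibody tags, so the fall may reflect the mutation or a difference in handling, which cannot be told apart.

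The second pattern is the larger mean share of Tfh-like cells in mutant libraries. Had the grouping of cells rested on the genes past the threshold, clustering without them would have left a difference under 6.39 percentage points. It left 11.8, so grouping by these genes is not its whole source. The naming of clusters still used them. In the main clustering, cluster 3 differed by 11.2 points and cluster 1 by 1.55. Cluster 3 took its Tfh name from Ascl2, Pdcd1, Tox2, Il21 and Sostdc1. Ascl2, Tox2 and Sostdc1 had passed the threshold, so the test cannot exclude that they set which clusters count as Tfh-like. The share in mutant 2 was 28.7%, within the WT range of 16.2% to 29.8%, but in 7 of 9 alternative clusterings it lay above both WT libraries. Whether the difference comes from mutant 1 alone therefore stays open, and no p under 0.333 is possible.

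The last pattern is the fall of immediate-early and stress genes, with a median of -0.38 over all kept T cells. With equal cluster shares the median was -0.36, past the bound of -0.19 (95% interval -0.47 to -0.21 over 28 genes). That interval treats the genes as independent and leaves out the spread between libraries. By the median alone, shares of these clusters are not its whole source. Within classes the median was -0.44 in naive or memory-like cells, -0.30 in cluster 0 and -0.22 in cluster 1 alone, but -0.14 in Tfh-like cells (clusters 1 and 3 pooled), which does not reach that bound. These genes respond within minutes to tissue processing, and the 2 libraries with antibody tags are both WT, so handling could account for the fall as well as genotype could.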

How the results depend on the processing

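With 2 libraries per genotype, most calls depended on WT 1 or mutant 1. The 178 kept cells of mutant 2 limit what can be tested within classes, and Il13 and Il17a were too scarce throughout. Over all kept T cells, 1217 gene values kept their direction and side of the threshold, 219 weakened, 74 gained a call and 32 reversed. In Tfh-like cells these were 277 kept, 34 weakened and 6 reversed. In naive or memory-like cells 171 were kept, 38 weakened, 1 gained and 3 reversed, and in cluster 0 121 were kept, 31 weakened and 8 reversed. For gene lists 222 were kept, 58 weakened, 12 gained and 3 reversed, for shares of cells with a UMI 71 were kept and 13 moved, and for the difference between classes 33 were kept, 36 weakened and 3 reversed. None of the reversed genes had passed the threshold except Cybb, Egr3 and Nfkbia. Pmepa1, Fos, Gpr83 and Ramp1 lost their calls only when other cell types were kept. Cluster 0 has no counterpart when cells are clustered again, so those settings gave no value for it. The cause of the changes below was not tested, except where fewer samples or genes are the change itself.

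All kept T cells gave 65 rises and 53 falls in edgeR. The DESeq2 Wald test gave 20 and 23 (Gata3 -0.000755, Xcl1 -0.38, Xbp1 -0.0143), no filter on low counts 202 and 157 (Xbp1 -0.00935), and the replicate block 187 and 130 (Xbp1 -0.0248). The labels do not say whether same-numbered libraries share an animal or a day. Their deviations correlated at 0.043 over 10612 genes and 0.0354 over 4329 genes above 32 CPM, which cannot exclude such sharing. With doublets kept Gata3 was -0.0135, and with doublets called on passing cells -0.0281. With other cell types kept the edgeR counts were 0 and 0, with 958 genes at an unadjusted p under 0.05 (Gata3 -0.0404, Plac8 1.14, Xcl1 -0.13, Xbp1 -0.0145, Krt18 1.33), where the common dispersion rose from 0.0114 to 0.0348; DESeq2 was not run there. Thinning gave 18 and 17 (Gata3 -0.0641) and leaving out the shallow cluster 30 and 29 (Tbx21 -0.18, Trac 0.00438). Equal cluster shares gave 6 and 10 (Bcl6 -0.15, Pdcd1 -0.22, Gata3 -0.12, Ifng -0.71, Eomes 0.63, Xbp1 -0.31). Leaving out 1 library gave 21 to 242 rises and 15 to 169 falls, fewest without WT 1 and most without mutant 2. Values then ran from -0.23 to 0.20 for Gata3, -0.15 to 0.0865 for Ikzf2, -0.57 to 2.12 for Tbx21, -0.42 to 0.0639 for Eomes, -2.34 to 0.47 for Xcl1, -0.34 to 0.19 for Xbp1 and -0.0392 to 0.32 for Pecam1.

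Tfh-like cells gave 9 rises and 9 falls in edgeR. The DESeq2 Wald test gave 0 and 1, with 164 genes at an unadjusted p under 0.05, and no filter on low counts gave 55 and 22. At most 5% mitochondrial UMIs gave 14 rises, doublets kept 20 rises, doublets called on passing cells 53 and 27, and Leiden resolution 1.2 gave 25 and 15. Clustering without the genes past the threshold gave 15 rises (Il4 0.0279, Gata3 -0.00862, Bcl6 0.0147), and cluster 1 alone 45 and 20. Leaving out 1 library gave 0 (edgeR, without WT 1, with 323 genes at an unadjusted p under 0.05) to 135 rises (without mutant 2) and 4 to 61 falls. Values then ran from -0.0318 to 0.16 for Ikzf2, -0.15 to 0.0291 for Pdcd1 and -0.0977 to 0.0373 for Bcl6.

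Naive or memory-like cells gave 7 rises and 8 falls in edgeR. The DESeq2 Wald test gave 1 and 1, no filter on low counts 4 rises, the replicate block 12 rises, at most 5% mitochondrial UMIs 21 and 24 (Ccr9 -0.29), doublets called on passing cells 4 rises, and clustering without the genes past the threshold 4 and 2. Leaving out 1 library gave 1 (without WT 1) to 30 rises (without mutant 1) and 1 to 20 falls, with Gata3 from -0.29 to 1.00 and Ccr7 from -0.57 to 0.0714. Cluster 0 gave 8 rises and 7 falls in edgeR. There DESeq2 size factors gave 4 falls, the DESeq2 Wald test 1 and 0 with 106 genes at an unadjusted p under 0.05 (Bcl6 -0.0371), no filter on low counts 13 and 20, and the replicate block 25 and 27 (Bcl6 -0.049). Leaving out 1 library gave 2 (without WT 1) to 18 rises (without mutant 1) and 2 to 19 falls, with Ifng from -0.29 to 2.10, Tgfbr1 from -0.79 to 0.0737, Cxcr5 from -0.0325 to 0.28 and Bcl6 from -0.81 to 0.30.

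The difference of the effect between Tfh-like cells and cluster 0 gave 7 higher and 2 lower genes in edgeR. No filter on low counts gave 11 higher, and the pair of Tfh-like and naive or memory-like cells, fitted first by mistake, gave 6 lower, with Cybb at -0.74. Cluster 1 against cluster 0, added later, gave 0 and 0 with 419 genes at an unadjusted p under 0.05 in edgeR (Nfkbia -0.16, Egr3 -0.16). Leaving out 1 library gave 2 (without WT 1) to 17 higher (without mutant 2) and 0 to 8 lower genes, the 0 with 353 genes at an unadjusted p under 0.05 in edgeR. Of 30 gene lists, 15 passed with camera, 0 with an estimated correlation, where 0 had an unadjusted p under 0.05, 1 with fry, and 4 with camera at equal cluster shares. Leaving out 1 library gave camera adjusted p from 0.00102 to 0.0875 for the interferon-signature markers, 5.97e-05 to 0.216 for interferon-stimulated genes and 0.0287 to 0.563 for T cell receptor targets. The naive or memory-like share differed by -13.7 percentage points at Leiden resolution 0.5. Of 20 key genes 11 had shares of cells with a UMI that did not overlap, and 7 at 750 UMIs per cell, where chance gives 33.3%.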

Other observations

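Plasma cells of the gut secrete IgA, and their transcripts can leak into droplets of other cells. Over kept T cells, in CPM without TMM scaling, Igha stood at 120 in WT 1 against 0.546 in WT 2, 0.531 in mutant 1 and 1.23 in mutant 2, and the light chain Igkc followed at 152, 3.64, 2.39 and 0.616 CPM. Whether these were free transcripts or came from plasma cells among the kept cells was not tested.

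The share of the epithelial-named cluster, with Reg3b and Reg3g from gut epithelium, varied too, at 1.86% and 7.18% of cells in the WT libraries and 6.09% and 8.72% in the mutant libraries.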
